A study of Mus musculus with 12 samples.

How the data were processed

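RNA from the mouse cell line C3H10T1/2 was measured on 12 Affymetrix arrays in 4 groups of 3, per the labels. Cells received a siRNA form of miR-140, a siRNA form of miR-96 as its control, an LNA oligonucleotide against miR-140, or an LNA oligonucleotide against miR-449 as its control. LNA (locked nucleic acid) is a modified nucleic acid that binds a microRNA tightly and blocks it. Total RNA was extracted with RNeasy columns and labelled with biotin, per the labels' protocols.

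The deposited values are log2 expression values made with RMA, per the submitters' processing notes. RMA corrects the background, brings arrays to a shared distribution and summarises the probes of a probe set. The RMA version and the probe set definition file were not given in the sources used here. The values range as RMA log2 values do, and the quartiles of the arrays lie close together within each experiment and apart between them. Whether the authors normalized the 2 experiments together is not given in the sources used here, but these quartiles argue against it.

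The table held 45101 probe sets, of which 64 array controls were left out of the tests and 45037 were tested, with no filter on level. Gene symbols came from the platform annotation. Of the tested probe sets, 34945 had 1 symbol, 932 had several and 9160 had none; 34741 of those with 1 symbol matched a gene ID of the mouse RefSeq table (GRCm38.p6), and 0 symbols changed. A gene was named only from a probe set with 1 symbol. Where 1 value per gene was needed, the probe set with the highest mean over all arrays was taken, which left 18193 genes. No genomic positions are given, since the deposited values name no genome build.

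Each probe set was fitted with limma 3.58.1 in R 4.3.3 as a model of 4 group means over all 12 arrays, with moderated variances (eBayes). The contrasts were siRNA-140 minus siRNA-96, anti-miR-140 minus anti-miR-449, the difference of these, and siRNA-96 minus anti-miR-449. Probe sets were called at a Benjamini-Hochberg adjusted p under 0.05 over the 45037 probe sets, and intervals are 95% intervals of the same fit. The overlap of the responses was tested with a two-sided Fisher's exact test, which takes probe sets as independent, and, added later, with 100 regroupings of the arrays within each experiment. Their correlation was tested with 100 such regroupings. In all, 31 gene lists were tested with limma's camera, a competitive test of a list against all other genes, with a preset correlation of 0.01, and again with an estimated correlation; limma's fry, which asks whether the genes of a list move one way on balance, stood beside them. The lists, microRNA targets included, were written from general knowledge without the literature at hand, so membership is approximate. List results were adjusted over the 31 lists. List means per array used members with a mean of at least 5.

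The contrasts, thresholds, gene lists, alternatives and the rule for named genes were fixed before the data were examined. The rule took, for each main contrast, up to 10 genes each way with an adjusted p under 0.05 and no overlap between the groups or, where none passed, the 5 each way with the smallest p. Genes that passed are given by their probe set with the largest change. It added up to 10 genes lower with siRNA-140 and higher with anti-miR-140, up to 4 members of each list described, and always Hdac4, Cxcl12, Smad3, Igfbp5, Adamts5, Pdgfra and Wwp2. Predicted genes without a name were passed over.

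Principal components and correlations between arrays were then computed within each experiment. A fit without siRNA-140 replicate 3 and siRNA-96 replicate 1 was added after these had been seen, on the other 10 arrays and on the 4 remaining siRNA arrays alone. Genes are named from it by the same rule, if called in both.

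The alternatives tried were a fit of the compared arrays alone, the replicate number as a block, a further quantile normalization, median centring, the probe sets whose mean is at or above the median, each array left out in turn, an intensity trend with robust variances, array weights, a fold threshold of 1.5, an unadjusted p, 1 probe set per gene, the mean of all probe sets of a gene, and an estimated correlation for lists. A planned test of genes with seed matches to miR-140 was not run, because no transcript sequences were at hand.

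The fit was tested on simulated data for 45037 probe sets with the spread of each experiment and known changes. The changes were placed in probe sets above the median level, and the noise was independent between arrays. For siRNA-140 against siRNA-96, the 12-array fit recovered 43.3% of true log2 changes of 0.5, 83.6% of changes of 1 and 100% of changes of 2, with 127 false calls. For anti-miR-140 against anti-miR-449 these were 38.8%, 88.1% and 100%, with 13 false calls. Without the 2 arrays, the 10-array fit of the siRNA comparison recovered 41.8%, 92.5% and 98.5% of changes of 0.5, 1 and 2 with 193 false calls, and the 4-array fit recovered 34.8% of changes of 2 and 0% of the smaller ones, with 0 false calls. The experiments share 1 variance in the 12-array model; fits of the 6 siRNA arrays alone recovered 0%, 46.3% and 86.4% of changes of 0.5, 1 and 2, with 1 false call, and fits of the 6 anti-miR arrays alone 55.2%, 94.0% and 100%, with 10. In the 12-array and 10-array fits of the siRNA comparison, false calls were above the share that the adjusted p allows. The real siRNA arrays divided across their labels, as described below, unlike the simulated noise. The recovery rates therefore do not tell what a count of 0 in the labelled comparison excludes. The number of arrays limits the precision of every value.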

Results

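C3H10T1/2 is a mouse embryonic cell line with properties of mesenchymal stem cells, able to form cartilage, bone, fat and muscle cells. miR-140 is a microRNA of cartilage, encoded within the gene Wwp2. A siRNA form of the microRNA (siRNA-140) was given to raise it and set against siRNA-96. An LNA oligonucleotide (anti-miR-140) was given to block it and set against anti-miR-449. Both controls act on another microRNA, so each difference joins an effect of miR-140 with that of miR-96 or miR-449. Each group had 3 arrays, which makes 12 arrays in 4 groups. The arrays do not measure mature microRNAs, so the level of miR-140 itself could not be read. The labels do not say whether replicates were separate cultures, so all p-values measure the spread between these samples.

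Median log2 values were 3.99, 4.02 and 3.95 in siRNA-140 replicates 1, 2 and 3, and 3.98, 3.96 and 4.0 in the siRNA-96 replicates. They were 4.36, 4.32 and 4.35 in the anti-miR-140 replicates and 4.32, 4.35 and 4.38 in the anti-miR-449 replicates.

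The first comparison asked which transcripts change when miR-140 is raised, set against miR-96. With the groups as labelled, no gene passed the test. Cxcl12, a chemokine that holds stem cells in their niche, read 9.54 ± 0.74 (SD, n = 3) with siRNA-140 and 9.90 ± 0.78 (n = 3) with siRNA-96, a log2 difference of -0.37 ± 0.35 (SE; 95% interval -1.12 to 0.38). Hdac4, a histone deacetylase of chondrocytes, differed by 0.06 ± 0.14 (interval -0.25 to 0.37), and Smad3, a transducer of TGF-beta signals, by -0.10 ± 0.19 (interval -0.50 to 0.30). Igfbp5, an IGF binding protein, differed by 0.16 ± 0.13, the matrix protease gene Adamts5 by -0.15 ± 0.19, the growth factor receptor gene Pdgfra by -0.01 ± 0.20 and Wwp2 by -0.07 ± 0.12. In the fit of the 6 siRNA arrays alone, which leaves out the narrower spread of the anti-miR arrays, the interval for Cxcl12 was -1.37 to 0.63.

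limma called 0 of 45037 probe sets, and the smallest adjusted p was 0.88. At an unadjusted p under 0.05 there were 2292 probe sets, 847 lower and 1445 higher with siRNA-140, where 2252 are expected by chance. A fit of the 6 siRNA arrays alone called 0 and had 1014 at that level. The genes with the smallest p, none significant, were Usp50 (0.55 ± 0.09), Brcc3 (0.71 ± 0.15), Fmn1 (0.49 ± 0.11), Slc24a2 (0.39 ± 0.09) and Sstr5 (0.52 ± 0.12) on the higher side. On the lower side they were Disp2 (-0.54 ± 0.09), Kansl3 (-0.49 ± 0.10), the interferon-induced kinase gene Cmpk2 (-1.04 ± 0.22), Lyrm1 (-0.48 ± 0.11) and Chek1 (-0.53 ± 0.12). Without siRNA-96 replicate 1 the fit called 36 probe sets, and without siRNA-96 replicate 2 it called 25, all lower with siRNA-140.

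Interferon response genes lay lower with siRNA-140, with a median log2 difference of -0.94 over 35 measured genes and a camera adjusted p of 1.05e-21. The adjusted p was 0.796 with an estimated correlation and 0.697 by fry, which called 0 of the 31 lists. None of the 35 passed over all probe sets; adjusted over the list alone, 1 did, Mx1 (-0.94 ± 0.22, adjusted p = 0.033), which encodes an antiviral GTPase. Smooth muscle and contractile genes had a median of -0.08 over 23 genes (camera adjusted p = 0.00819) and membrane traffic genes one of 0.08 over 30 genes (adjusted p = 0.032). Each of these had an adjusted p of at least 0.796 with an estimated correlation, and none of their members passed, over all probe sets or over the list alone. Myl9, a myosin light chain gene, differed by -0.80 ± 0.47 and Rab32, a gene of organelle traffic, by 0.52 ± 0.29. The 30 listed targets of miR-140 had a median of 0.05 and a mean of 0.02, against a camera direction of lower (adjusted p = 0.994), and 0 members passed over all probe sets or adjusted over the list alone. The list was written from general knowledge. It holds Cxcl12, and whether that gene was first named a target from these samples is not given in the sources used here, so its direction is not taken as independent evidence. The 27 measured targets of miR-96 had a median of 0.17 (adjusted p = 0.0535). The number of lists called, 3, became 1 without siRNA-140 replicate 1, siRNA-140 replicate 2, siRNA-96 replicate 2 or siRNA-96 replicate 3. It became 5 without siRNA-140 replicate 3 and 7 without siRNA-96 replicate 1.

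The siRNA arrays did not group by their labels. The first principal component held 53.21% of their variance and gave -25.2, -34.18 and 28.42 for siRNA-140 replicates 1, 2 and 3, and -33.11, 32.39 and 31.68 for siRNA-96 replicates 1, 2 and 3. The array most like siRNA-140 replicate 3 was siRNA-96 replicate 2 (r = 0.9976 across probe sets), and the array most like siRNA-96 replicate 1 was siRNA-140 replicate 1 (r = 0.9952). Probe sets are not independent replicates, so these r values only order the arrays.

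**Figure D1:**
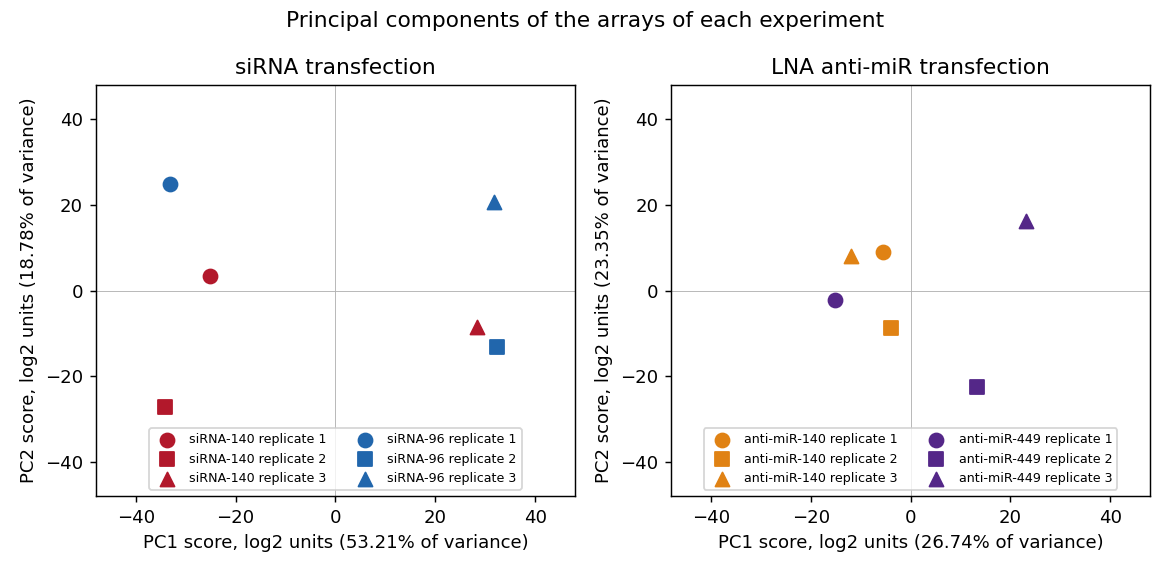
Scores of the arrays on the first and second principal components, computed within each experiment, in log2 units; colour gives the group and shape the replicate. On the first component of the siRNA arrays, siRNA-140 replicate 3 (28.42) lies with siRNA-96 replicates 2 and 3, and siRNA-96 replicate 1 (-33.11) lies with siRNA-140 replicates 1 and 2.

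Single genes showed the same arrangement. Vnn1, which encodes an enzyme that releases pantothenate, read 8.03 and 8.34 in siRNA-140 replicates 1 and 2 and 8.22 in siRNA-96 replicate 1. It read 2.84 in siRNA-140 replicate 3 and 2.84 and 3.04 in siRNA-96 replicates 2 and 3. Postn, which encodes the matrix protein periostin, read 6.61, 6.17 and 10.01 in siRNA-140 replicates 1, 2 and 3, against 6.23, 10.06 and 10.16 in siRNA-96 replicates 1, 2 and 3. Cxcl12 read 9.11, 9.11 and 10.39 with siRNA-140 and 9.01, 10.40 and 10.30 with siRNA-96. Usp18, a protease gene induced by interferon, read 3.85, 4.67 and 8.01 with siRNA-140 and 4.65, 8.92 and 9.30 with siRNA-96. Signal of the 18S ribosomal RNA controls was 10.47 in siRNA-96 replicate 1 and 7.86 in siRNA-96 replicate 3, against 5.40 to 6.73 in the other siRNA arrays.

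**Figure D2:**
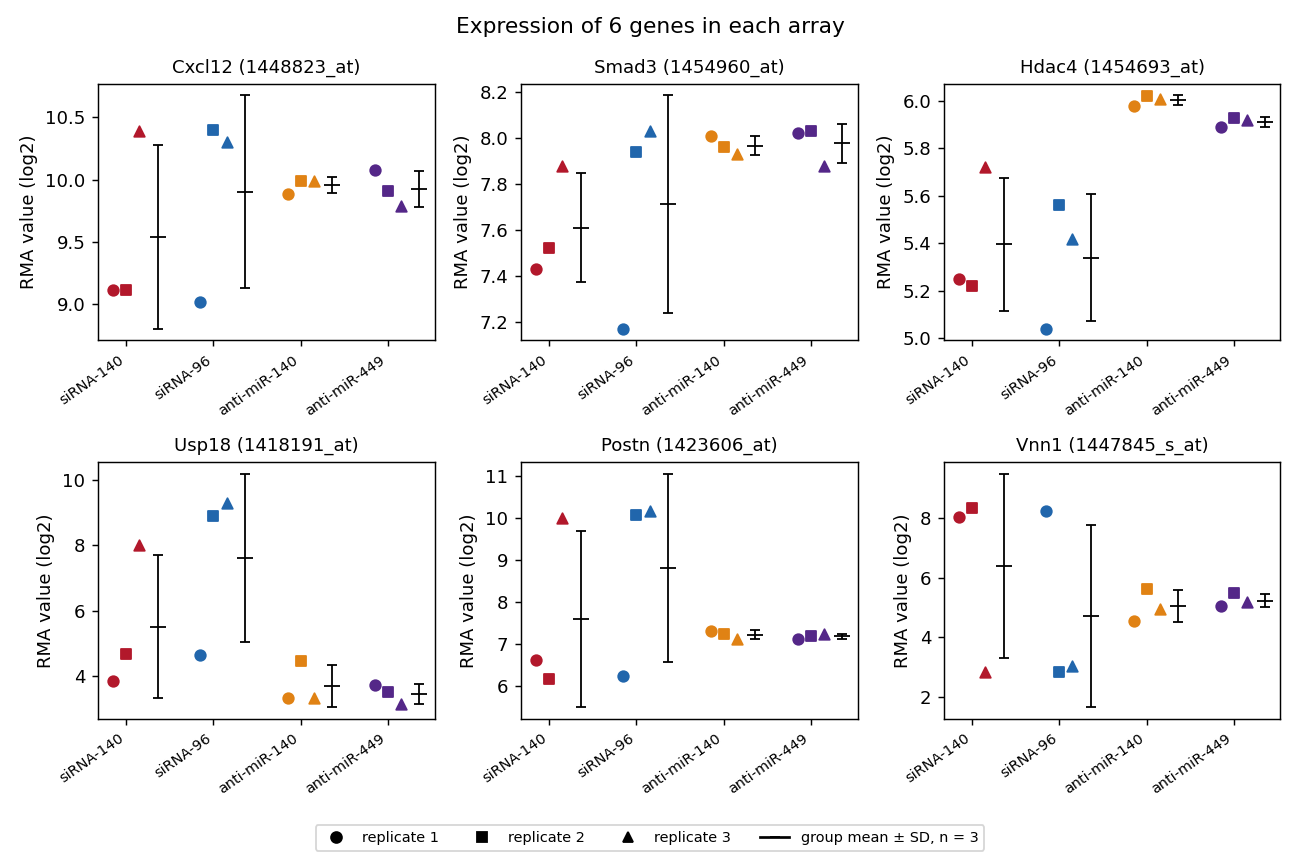
RMA values (log2) of 6 genes in each array, with the group mean and SD (n = 3) beside the points. For Vnn1, Postn, Usp18 and Cxcl12, siRNA-140 replicate 3 and siRNA-96 replicate 1 each lie with the other group's remaining arrays, while the anti-miR arrays show no such division.

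Without these 2 arrays, siRNA-140 replicates 1 and 2 (n = 2) differed from siRNA-96 replicates 2 and 3 (n = 2) at many genes. Interferon-induced genes were the most strongly lower: the GTPase gene Iigp1 by -5.27 ± 0.31 (SE; limma adjusted p = 5.03e-07), Usp18 by -4.85 ± 0.35, Oasl2 by -4.74 ± 0.20, Ifit1 by -4.02 ± 0.46 and Ifit3 by -3.99 ± 0.26. Postn was lower by -3.72 ± 0.14 (adjusted p = 3.72e-08), and Rsad2, Trim30a, Rtp4 and Gbp3 by between -3.64 and -3.47. Vnn1 was higher by 5.25 ± 0.26 (adjusted p = 1.45e-07), Dynap by 3.71 ± 0.19, Igfbp4, an IGF binding protein gene, by 3.10 ± 0.17 and the membrane raft gene Mal by 3.06 ± 0.13. Slurp1, the mesothelin gene Msln, Rhpn2, the sphingomyelin synthase gene Sgms2, Vat1 and the integrin gene Itgb4 were higher by 2.00 to 2.58. Each gene is given here by its probe set with the largest change, so other probe sets gave less: -3.74 for Iigp1, 0.64 to 2.33 for Igfbp4, 1.71 for Mal, 0.52 for Sgms2, -0.61 for Rtp4, and -1.98 and -2.99 for Rsad2.

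Of the 7 genes followed throughout, Cxcl12 was lower by -1.24 ± 0.12 in that setting (adjusted p = 2.17e-05 with 10 arrays and 0.000932 with 4). Its other bright probe set gave -1.66, and its dim probe set gave 0.04 (adjusted p = 0.916). Smad3 gave -0.51 ± 0.11 (limma adjusted p = 0.0076) and Pdgfra -0.45 ± 0.11 (adjusted p = 0.0246), but neither passed with 4 arrays (adjusted p = 0.0868 and 0.168). The dimmer Smad3 probe sets gave -0.03 (adjusted p = 0.945) and -0.635 (adjusted p = 0.0687), so neither passed. A dimmer Pdgfra probe set passed the other way, at 0.54 (adjusted p = 0.0261). The remaining Pdgfra probe set gave -0.20 (adjusted p = 0.666), so no direction is given for Pdgfra. Adamts5 gave -0.53 ± 0.15 (adjusted p = 0.0503), with -0.37 (adjusted p = 0.0492) and -0.36 (adjusted p = 0.212) at its other bright probe sets. Hdac4 gave -0.26 ± 0.10 (adjusted p = 0.155), Wwp2 -0.27 ± 0.11 (0.197) and Igfbp5 0.17 ± 0.17 (0.652).

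The 10-array fit called 4043 probe sets, 1733 lower and 2310 higher. In the simulation this fit made 193 false calls beside 28, 62 and 65 recovered changes. Under those simulated conditions its adjusted p did not hold false calls to the nominal share. The simulation took the observed spread of each probe set in each experiment as its true spread. It therefore does not give the rate of false calls among the real ones. The 4-array fit called 1743, of which 1735 were called in both: 830 lower and 905 higher, in 566 and 598 genes. At least 2-fold changes made up 301 of the lower and 234 of the higher. The 2 arrays were left out after their values had been seen, and because of the profile that is then compared, so these adjusted p-values are not independent evidence of an effect of miR-140.

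The errors and member counts that follow rest on the 10-array fit, whose adjusted p-values did not hold their rate in the simulation. In that setting fry called 15 of the 31 lists, camera 7, and camera with an estimated correlation 2. In it 32 of 35 interferon response genes were lower (median -1.92; adjusted p = 4.87e-49, and 0.026 with an estimated correlation). Of the 23 smooth muscle and contractile genes, 10 were lower and 0 higher (adjusted p = 8.29e-11, and 0.026 with an estimated correlation), among them Myl9 (-1.98 ± 0.15), the actin genes Actg2 (-1.68 ± 0.14) and Acta2 (-0.87 ± 0.10), and Cald1 (-0.98 ± 0.10). Of 27 listed miR-96 targets, 9 were higher and 2 lower (adjusted p = 0.00196, and 0.161 with an estimated correlation), with Mitf, a transcription factor of pigment cells, higher by 1.92 ± 0.15, the water channel gene Aqp5 by 1.60 ± 0.12 and the growth factor gene Hbegf by 1.05 ± 0.13. Of 30 listed miR-140 targets, 5 were lower and 3 higher, or 6 and 5 adjusted over the list alone (adjusted p = 0.231 for the list); Bmpr2 (-0.76 ± 0.11) and the Notch ligand gene Jag1 (-1.03 ± 0.19) were lower with Cxcl12, and Mmd (1.15 ± 0.13) was higher. TGF-beta and BMP pathway genes were lower in 11 and higher in 4 of 39 (adjusted p = 0.00367, and 0.477 with an estimated correlation), with Tgfb2 at -1.88 ± 0.14. Wnt pathway genes were lower in 10 and higher in 1 of 39 (0.00367, and adjusted p = 0.0756 with an estimated correlation), with Sfrp1 at -1.03 ± 0.11. Extracellular matrix genes were lower in 10 and higher in 4 of 38 (0.00539, and adjusted p = 0.498 with an estimated correlation), with Col3a1 at -1.12 ± 0.10. Membrane traffic genes were higher in 7 of 30 (0.00201, and adjusted p = 0.27 with an estimated correlation), with Rab32 at 1.23 ± 0.14.

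**Figure D3:**
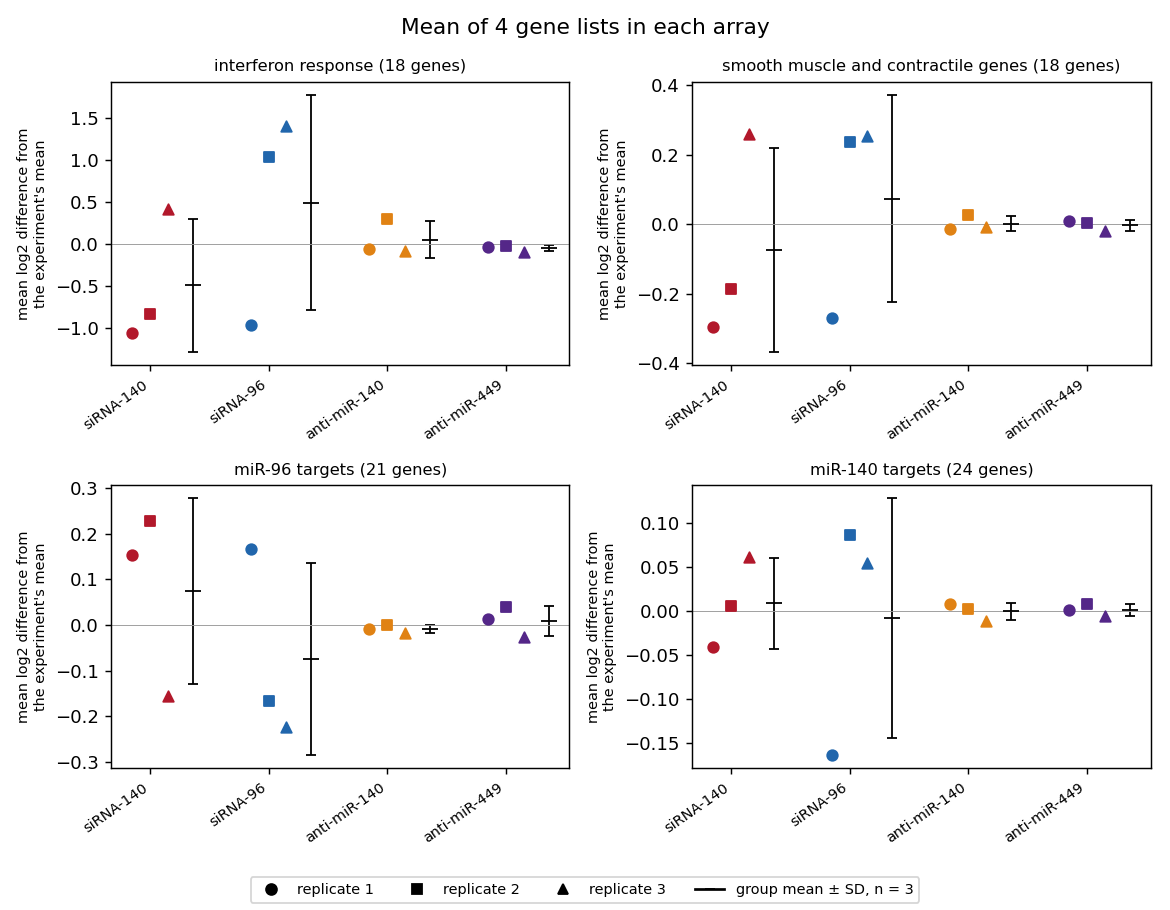
Mean log2 difference of each array from its experiment's mean over the members of 4 gene lists with a mean of at least 5, with the group mean and SD (n = 3). In the interferon list siRNA-96 replicate 1 (-0.97) lies with siRNA-140 replicates 1 and 2 (-1.06 and -0.84), and siRNA-140 replicate 3 (0.42) lies between those and siRNA-96 replicates 2 and 3 (1.04 and 1.41).

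The second comparison asked which transcripts change when endogenous miR-140 is blocked, set against a block of miR-449. No gene passed the test. Cxcl12 read 9.95 ± 0.06 (SD, n = 3) with anti-miR-140 and 9.93 ± 0.15 (n = 3) with anti-miR-449, a difference of 0.03 ± 0.35 (SE; 95% interval -0.72 to 0.78). Hdac4 read 6.003 ± 0.021 against 5.913 ± 0.021, a difference of 0.09 ± 0.14 (interval -0.22 to 0.40). Its dimmer probe sets gave -0.06 and -0.07. Smad3 differed by -0.01 ± 0.19, with -0.06 and 0.33 at its dimmer probe sets. Igfbp5 differed by 0.03 ± 0.13, Adamts5 by -0.20 ± 0.19, Pdgfra by -0.07 ± 0.20 and Wwp2 by -0.03 ± 0.12. These errors come from the variance shared by all 12 arrays, to which the siRNA arrays add their wider spread. In the fit of the 6 anti-miR arrays alone, the difference was 0.09 ± 0.07 (interval -0.06 to 0.24) for Hdac4 and 0.03 ± 0.09 (interval -0.18 to 0.23) for Cxcl12, and the adjusted p was 0.974 and 0.996.

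limma called 0 probe sets, with a smallest adjusted p of 1, and 1022 at an unadjusted p under 0.05, of which 601 were lower and 421 higher, where 2252 are expected. A fit of the 6 anti-miR arrays alone also called 0 and had 2148 at that level. The genes with the smallest p, none significant, were Cfap97 (0.56 ± 0.14), Cipc (0.36 ± 0.09), Nsd3 (0.43 ± 0.11), the Polycomb gene Eed (0.39 ± 0.10) and Ercc6l2 (0.33 ± 0.09) on the higher side. On the lower side they were Zdbf2 (-0.43 ± 0.08), H1f6 (-0.41 ± 0.10), Wdr18 (-0.39 ± 0.09), Cd3g (-0.47 ± 0.12) and Fgf11 (-0.54 ± 0.14). The first principal component of these arrays held 26.74% of the variance. It gave -5.54, -3.97 and -11.9 for anti-miR-140 replicates 1, 2 and 3 and -15.2, 13.4 and 23.2 for anti-miR-449 replicates 1, 2 and 3, so that anti-miR-449 replicate 1 lay with the anti-miR-140 arrays. Leaving out that array also gave 0 calls.

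With anti-miR-140, 4 gene lists passed camera with the preset correlation, and none did with an estimated one or by fry. Genes of DNA replication had a median log2 difference of 0.05 over 36 genes (camera adjusted p = 0.000553, and adjusted p = 0.954 with an estimated correlation), and Ccne2, a cyclin gene, differed by 0.26 ± 0.12. Ccne2 is also on the list of miR-34 and miR-449 targets, and the control here was anti-miR-449. A target released by that control would read lower, not higher, in this difference. Genes of mitosis had a median of 0.05 over 39 genes (adjusted p = 0.0111, and adjusted p = 0.954 with an estimated correlation), and the kinesin gene Kif11 differed by 0.19 ± 0.12. Immediate early genes had a median of 0.08 over 30 genes (adjusted p = 0.015, and adjusted p = 0.904 with an estimated correlation), with Fosb at 0.54 ± 0.28 and Fos at 0.34 ± 0.22. Endothelial genes had a median of -0.07 over 16 genes (adjusted p = 0.0323, and adjusted p = 0.904 with an estimated correlation), with the tight junction gene Cldn5 at -0.33 ± 0.12. None of the members of these lists passed, over all probe sets or over the list alone. The replication list had array means of 0.05, 0.01 and 0.04 with anti-miR-140 and 0.08, -0.07 and -0.11 with anti-miR-449. The 30 listed miR-140 targets had a median of 0.00 and a mean of -0.02 (adjusted p = 0.909), with 0 members past the test over all probe sets or adjusted over the list alone. The 28 measured targets of miR-34 and miR-449 had a median of -0.00333 and a mean of -0.00488 (camera adjusted p = 0.909), also with 0 members past the test. The number of lists called, 4, became 0 without anti-miR-449 replicate 3, and 1 without anti-miR-449 replicate 2, without anti-miR-140 replicate 1 or after a further quantile normalization.

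The experiments together ask which transcripts fall when miR-140 is raised and rise when it is blocked, as direct targets would. No probe set passed the limma test in both with that pattern. At an unadjusted p under 0.05 in both, 6 probe sets did, where 7.92 are expected (two-sided Fisher's exact p = 0.716 unadjusted and adjusted over the 4 direction pairs; 59 of 100 regroupings of the arrays within the experiments, the real one included, lay as far from expectation). They held 4 named genes: Eed differed by -0.36 ± 0.10 with siRNA-140 and 0.39 ± 0.10 with anti-miR-140, Pcdh18 by -0.27 ± 0.11 and 0.41 ± 0.11, Tmem35a by -0.25 ± 0.10 and 0.21 ± 0.10, and Slc6a20b by -0.20 ± 0.09 and 0.22 ± 0.09. Probe sets higher in both numbered 30 against 13.5 expected, those lower in both 19 against 11.3, and those higher with siRNA-140 and lower with anti-miR-140 16 against 19.3. Fisher's test gave adjusted p = 0.000254, 0.064 and 0.716, but it takes probe sets as independent; of the 100 regroupings 15, 31 and 77 lay as far from expectation, so none of these stands out. Without the 2 siRNA arrays the opposite pattern held 56 probe sets against 52.5 expected, those higher in both 90 against 80.3, those lower in both 40 against 67.3, and those higher with siRNA-140 and lower with anti-miR-140 61 against 103. Fisher's adjusted p was 0.611, 0.337, 0.000482 and 1.05e-05, and 93, 85, 36 and 33 of 100 regroupings lay as far from expectation. Across the 45037 probe sets, which are not independent replicates, the responses had a Pearson r of 0.0578 and a Spearman rho of 0.0615. Of 100 regroupings of the arrays within the experiments, the real one included, 34 gave an r and 35 a rho at least as far from 0. The difference between the responses passed for 0 probe sets by limma, with 1322 at an unadjusted p under 0.05, where 2252 are expected; without the 2 siRNA arrays it passed for 1985.

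The control arms, siRNA-96 and anti-miR-449, were compared to describe how far the experiments stood apart. Experiment, delivered molecule and microRNA differ together here and cannot be told apart. Among single genes, the interferon-induced Ifit1 read 7.97 in siRNA-96 against 3.20 in anti-miR-449 (4.77 ± 0.96; limma adjusted p = 0.00143), with 5.20, 9.0 and 9.71 in siRNA-96 replicates 1, 2 and 3. Usp18 read 7.62 against 3.45 (4.17 ± 1.09) and Irf7, a transcription factor of the interferon response, 6.73 against 3.75 (2.97 ± 0.54). Ifit1 and Usp18 also divided the siRNA arrays among themselves. Between siRNA-140 replicates 1 and 2 and siRNA-96 replicates 2 and 3 they differed by -4.02 and -4.85. Their control-arm differences therefore do not measure a gap between the experiments alone. The cell adhesion gene Jam2 read 3.36 in siRNA-96 and 5.60 in anti-miR-449 (-2.25 ± 0.40), and the G protein gene Gng12 6.96 and 8.97 (-2.02 ± 0.20). These control-arm genes were chosen after their values were seen. Only genes called with the same direction before and after a further quantile normalization could be chosen. In all, 25017 probe sets differed, 24361 lower and 656 higher in siRNA-96, with a median log2 difference of -0.33. After a further quantile normalization, which removes that shift, 7462 differed, 3792 lower and 3670 higher. Ifit1 then gave 5.14 and Gng12 -1.67. That the named genes kept their direction follows from how they were chosen and is no check of it.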

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

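Apart from the camera tests, whose contrast and lists were fixed beforehand, and the splits of the arrays for lists, control arms and joint results, the tests in this part were chosen after the result they bear on had been seen. The response of 3 gene lists differed between the siRNA and anti-miR experiments by camera, as the mean log2 difference between the responses. It was -1.04 for the interferon response (adjusted p = 1.49e-17), -0.16 for smooth muscle and contractile genes (adjusted p = 0.0253) and 0.23 for miR-96 targets (adjusted p = 0.0382). For each, the adjusted p was 0.867 with an estimated correlation.

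The arrays siRNA-140 replicate 3 and siRNA-96 replicate 1 each carried the profile of the other group. For amount and quality of the hybridized RNA there were 7 measures. They were 5 control groups that vary between the arrays and 2 differences of 3 prime and 5 prime signal. Of these, 0 separated the arrays the way the profile did. Of all 10 control groups 1 did, as many as chance gives: the Bacillus controls near background (2.20 to 2.29 against 2.16 to 2.20). The measures are not independent checks, since the BioB, BioC, BioD and Cre controls rose and fell together. Gapdh and beta-actin read near the top of the scale, so their 3 prime and 5 prime differences say little about quality. Amount as the whole cause of this profile is thus argued against, and quality is not decided. Positions were read on the 21 expressed miR-96 targets, where 0 is the mean of siRNA-96 replicates 2 and 3. On that scale 1 is the mean of siRNA-140 replicates 1 and 2. Replicate 3 of siRNA-140 lay at 0.128 and siRNA-96 replicate 1 at 1.09. Of 2000 lists of other genes that differ as much, the middle 95% gave -0.04 to 0.22 and 0.76 to 1.11. The 2 arrays lay at percentiles 82.1 and 95.4 of those lists, the second near the upper limit. Exchanged labels may account for the profile, but these targets do not single that out. Correct labels with 2 separate preparations cannot be told apart from this, since no label names a preparation and the difference of siRNA-96 minus siRNA-140 within each set of like arrays was -0.0308 (95% bootstrap interval over genes -0.07 to 0.01) over the same targets, with the size of a miR-96 effect unknown; siRNA-96 replicates 2 and 3 minus siRNA-140 replicates 1 and 2 gave -0.39 (-0.66 to -0.14), which an exchange and a preparation both allow, and the labelled odd arrays ranked 3 of 9 pairs (r = 0.12), too few to decide. As the labels are in doubt, the labelled comparison cannot settle an effect of the siRNAs themselves. No fit of all probe sets with the sets of like arrays as blocks was run. On the interferon list siRNA-140 replicate 3 read 0.42 against 1.04 and 1.41 in its like arrays.

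The siRNA-96 arrays read lower than the anti-miR-449 arrays at 97.4% of the probe sets called. RMA of all arrays together would bring them to a shared distribution. Medians instead lay at 3.95 to 4.02 in the siRNA arrays and 4.32 to 4.38 in the anti-miR arrays. Lower quartiles lay at 2.63 to 2.7 and 2.96 to 3.03, and upper quartiles at 6.52 to 6.68 and 6.89 to 6.95. For the shift shared by most probe sets, these values argue against normalization together and for normalization of the 2 experiments apart. The 27 Bacillus control probe sets, for which mouse cells have no transcript, also differed, by -0.28 on average. An effect of the siRNA or of the transfection reagent on mouse genes would not act on those probe sets directly. Normalization ties each probe set to the whole distribution, so their shift does not exclude such an effect. Such an effect may also add to the differences that remain after a further quantile normalization, where 50.8% of calls were lower. No biological explanation was tested.

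For siRNA-140 against siRNA-96 there are 10 splits of the 6 arrays, too few for a share under 0.05; the real one called 0 probe sets and the highest other 5863. That other split sets siRNA-140 replicates 1 and 2 with siRNA-96 replicate 1, and points to a structure of the samples. For lists the real split called 3 and the highest other 12, which is that same split, and 9 of 10 gave at least as many. For anti-miR-140 against anti-miR-449, also with 10 splits, the real one called 0 probe sets and the highest other 8; for lists the real one called 4 and the highest other 4, with 2 of 10 at least as high. For the control arms the real split called 25017 and the highest other 0, with 1 of 10 as high, and 10 splits are again too few. For the correlation of the responses, chance could not be excluded with 100 regroupings of both experiments (real 0.0578, highest other 0.193, 34 as far from 0). The opposite response (real 0, highest other 3) and the difference between the responses (real 0, highest other 3111) were regrouped in the same way. Where the real count is 0, every split is at least as high by construction (10 of 10 or 100 of 100), so those counts say nothing about chance.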

How the results depend on the processing

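The settings without 2 siRNA arrays were chosen after the data had been seen; the others were planned. The count of 0 for siRNA-140 against siRNA-96 held in the fit of the compared arrays alone, with quantile normalization, median centring, the brighter probe sets, trend and robust variances, array weights, the fold threshold and 1 probe set per gene. It became 2292 at an unadjusted p, 4043 leaving aside 2 arrays in doubt and 1743 with only the 4 siRNA arrays fitted. The count of 0 for anti-miR-140 moved only at an unadjusted p, to 1022. The opposite response (0) moved only there, to 6, and the difference between the responses (0) to 1322 there and to 1985 without the 2 arrays. The control arms (25017) gave 7462 after quantile normalization, 7353 after median centring (3147 lower, 4206 higher), 8088 at 1.5-fold or more, and, with fewer probe sets tested, 12805 for the brighter ones and 10618 with 1 per gene; the scaling removes the shift between experiments. Lists with siRNA-140 (3) fell to 0 with an estimated correlation and were 7 without the 2 arrays; lists with anti-miR-140 (4) fell to 0 with an estimated correlation and 1 after quantile normalization. Leaving out each array in turn gave 0 to 36 calls for siRNA-140, 0 to 1 for the difference between responses, 20287 to 25824 for the control arms, 1 to 7 lists with siRNA-140, 0 to 4 lists with anti-miR-140, and a correlation of -0.00967 to 0.0859; anti-miR-140 and the opposite response stayed at 0. Except where a setting's construction shows it, the cause was not tested. Replicate numbers did not pair the arrays (deviations of same-numbered arrays correlated at 0.41, -0.241 and 0.439 for siRNA and -0.0137, 0.103 and -0.0316 for anti-miR, and in each experiment 2 of 6 arrays correlated best with their own number); with the replicate number as a block the counts were 0 for both main comparisons, the opposite response and the difference, 25196 for the control arms, 4 and 3 lists, and 0.0578 for the correlation. In all, 143 of 172 values of these results stayed within their tolerance and 29 moved. The tolerance was 1.5-fold for a count, and a count of 0 had to stay 0. For the correlation it was 0.0652, the SD over the regroupings, which is wide enough to include a correlation of 0. The 143 include many counts of 0 that stayed 0. Of 819 values of named genes, 0 changed sign with a call, 15 passed the test only in the alternative, 11 of them in the 10-array setting, and 21 uncalled values changed sign. Seed matches to miR-140 were not run, for want of transcript sequences. Signal near background limits genes such as Usp50 and Eed, which read below the median of their arrays.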

Other observations

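The tests here were not planned. Without the 2 siRNA arrays in doubt, 8 gene lists passed fry but not camera. Of 27 p53 target genes 5 were lower in siRNA-140 replicates 1 and 2 and 0 higher, or 6 and 2 adjusted over the list alone, among them Trp53inp1 (-1.28 ± 0.10) and Btg2 (-1.06 ± 0.12); the adjusted p was 0.0404 by fry, 0.0821 by camera and 0.552 with an estimated correlation. Of 31 genes of the unfolded protein response 6 were higher and 1 lower, or 9 and 2 over the list alone (0.00902, 0.194 and 0.498 in the same order), with Trib3 at 0.58 ± 0.12 and Dnajb9 at -0.77 ± 0.11. Of 31 inflammatory genes 6 were lower and 3 higher, or 7 and 3 over the list alone (0.0349, 0.197 and 0.477), with Tnfaip3 at -1.26 ± 0.11 and Ptgs2 at 0.82 ± 0.11. The other 5 were chondrogenic (fry adjusted p = 0.0487), osteogenic (0.0213), adipogenic (0.0404), cholesterol synthesis (0.0317) and histone deacetylase genes (0.028). In the same order, camera with an estimated correlation gave adjusted p = 0.477, 0.27, 0.641, 0.557 and 0.477. Their lower and higher members numbered 3 and 0, 3 and 1, 0 and 2, 1 and 3, and 1 and 0. Over all 45037 probe sets the same fit called 1733 lower and 2310 higher. Counts this small are therefore not read as a result about these lists. Targets of miR-34 and miR-449 passed neither (fry adjusted p = 0.13, camera adjusted p = 0.194): of 28 measured, 5 were lower and 2 higher, over all probe sets and over the list alone, with E2f5 at 1.30 ± 0.14.

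Among the 4 siRNA arrays left in that setting, the 21 expressed miR-96 targets had a median log2 difference of 0.34, higher in siRNA-140. It lay at percentile 99.99 of 10000 random lists of the same size matched on level, which describes these arrays and is no test of the treatment.

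The 18S ribosomal RNA controls read 10.23 in anti-miR-449 replicate 1, against 5.92 to 6.75 in the other anti-miR arrays, and 10.47 in siRNA-96 replicate 1. The BioB hybridization controls read 9.16 in siRNA-96 replicate 1 and 8.17 in siRNA-96 replicate 3, against 6.94 to 7.59 in the other siRNA arrays and 7.41 to 7.72 in the anti-miR arrays.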
